A study of Arabidopsis thaliana with 8 samples.

How the data were processed

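Steady-state transcript levels were measured by RNA sequencing in Arabidopsis thaliana of the Col-0 background. Wild-type plants (wt) were set against clf-28, an insertion allele of CURLY LEAF (CLF), which encodes a histone H3 lysine 27 methyltransferase of the Polycomb system. The labels give 8 libraries, 1 per genotype in each of 4 organs: roots, leaves, flowers and siliques. The libraries called leaves were collected as the aerial part. Roots and aerial parts came from plants 2 weeks old on plates, and flowers and siliques from plants 5 weeks old in soil, all in long days at 22 °C. RNA was purified on columns with DNase treatment, made into TruSeq version 2 libraries and sequenced on a HiSeq 2000.

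The authors named TopHat, Cufflinks and the TAIR10 genome in their processing notes, without versions. The deposited table is a Cufflinks gene table of 34759 loci, and per the file headers it gives an FPKM (fragments scaled to transcript length and to mapped fragments), a lower and an upper bound and a status for every locus and library. The FPKM values and both bounds were used as deposited. The status column, of unit other, is the authors' quantification flag: a usable value, too few reads, too many reads or a failed fit. Whether the authors scaled libraries against each other is not stated. Sums of FPKM per library ran from 656178 to 715547. Read counts were not used here, so the depth of each library is unknown and no counting interval could be computed. The precision behind a value is therefore the authors' interval, which was wide: the median upper bound was 2.37 to 2.42 times the FPKM, and the lower bound was 0 for 89.3% to 91.0% of genes with at least 1 FPKM. Loci that Cufflinks gave several gene names (1098) were kept as merged loci and entered no gene list. Positions are those of the deposited loci on TAIR10, with starts counted from 1, and symbols came from the RefSeq gene table, whose gene overlapped the deposited locus for 99.8% of matched genes.

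Values were transformed as log2(FPKM + 1). Within an organ, a gene was measured when its status was usable in both libraries and at least 1 of them had 1 FPKM or more. With 1 library per genotype and organ, no test within an organ was possible, and genes were described by a rule of size: at least 2-fold higher or lower in clf-28, that is a log2 ratio of at least 1 or at most -1. The only replication of the genotype was over organs. A linear model in limma 3.58.1 (R 4.3.3), with a mean-variance trend and organ as a block of 4 pairs, tested 24078 genes with usable status in all 8 libraries and 1 FPKM or more in at least 1. The clf-28 effect was tested over the 4 organs (3 residual degrees of freedom). In a fit with genotype nested in stage (2 residual degrees of freedom) it was tested in the seedling organs (roots and leaves), in the reproductive organs (flowers and siliques), and as the difference between these stages. P values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Tables and percentiles were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

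There were 17 gene lists: textbook CLF targets, Polycomb and related chromatin factors, floral organ identity, flowering time, KNOX and meristem, embryo and seed maturation regulators, seed storage with oleosin and LEA, fatty acid and oil synthesis, endosperm and seed coat, anther and pollen, photosynthesis, root and root hair, defence and jasmonate, cold with drought and ABA response, heat shock, auxin, and reference genes. Of 315 distinct list genes, 304 had a locus of their own. Lists of at least 5 tested genes were compared with all other tested genes by camera in limma with a preset correlation of 0.01, and again with the correlation estimated from the residuals. The estimated form also takes the residual degrees of freedom of the fit, 3 over organs and 2 by stage. A p can therefore rise where genes are not correlated. For auxin over organs the estimated correlation was -0.0012, and p went from 0.0625 to 0.134 in camera. With fry, each list was tested against no change. Within an organ, the median log2 ratio of a list of at least 5 measured genes was given its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A list was counted as outside the central 95% below percentile 2.5 or above 97.5. The random lists hold independently drawn genes, so the percentile does not allow for genes of a list that move together.

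Samples, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Per organ, the rule takes up to 6 of the largest rises and up to 6 of the largest falls in log2 ratio among measured genes whose authors' intervals did not overlap. Over organs, since fewer than 5 genes passed, it takes the 5 smallest p in each direction among genes with the same sign in 4 of 4 organs. For the difference between stages it gives the count alone when no gene passes. It adds CLF, every textbook target in every organ, and in each list described 2 to 4 members with the largest absolute log2 ratio in that comparison. Other genes that are named were chosen after their values were seen, and the text says so. The value of 1 gene that the rule takes is not reported here.

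Alternatives were another pseudocount, another filter on low values, median-of-ratios or quantile scaling, another prior or no trend in limma, no organ block, each organ left out in turn, an estimated correlation for the lists, and the added demand that the authors' intervals do not overlap. Leaving siliques out of the overlap of organs and of the lists within organs, and other pseudocounts and scaling for CLF, were added after the data were seen. The limma fit was tested on simulated data with the spread of the real genes: of 50 genes each changed by 2, 4, 8 and 16-fold in 4 organs it called 50%, 86%, 82% and 94%, and it called 5 of the unchanged genes. The changed genes were drawn from those of higher mean expression and shifted alike in each organ. These shares do not hold for genes of low FPKM or of uneven change. Every per-sample column of the table was read. Genes with any status other than usable in 1 of the 8 libraries (440) were left out of the model.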

Results

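Transcript levels were compared between wt and clf-28 in roots, leaves, flowers and siliques, with 1 library in each of the 8 groups. No group has replicates, so no value below carries a replicate error. Differences within an organ are described by their size, and only effects shared over organs were tested. Between 17925 genes (wt leaves) and 20574 genes (wt flowers) had at least 1 FPKM in a library. The depth of the libraries is unknown.

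The mutated gene was looked at first. CLF (AT2G23380, chromosome 2, 9955553 to 9960359) was at 17.2 FPKM in wt roots and 7.84 in clf-28 roots, a log2 ratio of -1.04. It was at 6.57 and 5.50 FPKM in leaves, 9.99 and 14.7 in flowers, and 6.53 and 15.1 in siliques, with log2 ratios of -0.22, 0.52 and 1.1. The authors' intervals of wt and clf-28 overlapped in each organ, and the gene-level value counts reads from the whole locus, so the insertion was not visible in it.

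Organ markers, chosen after their values were seen, followed the organ labels. The pollen coat gene GRP17 was at 563 FPKM in wt flowers and 333 in clf-28 flowers, and at most 6.37 in siliques. The iron transporter IRT1 was at 373 FPKM in wt roots and 159 in clf-28 roots. Roots also held transcripts of green tissue, more in wt than in clf-28: RBCS1A, the small subunit of Rubisco, was at 89.3 FPKM in wt roots and 52.7 in clf-28 roots, against 5998 FPKM in wt flowers. Seed storage transcripts were present in wt roots, with the 2S albumin SESA5 at 10.8 FPKM, and nearly absent from clf-28 roots, where it was at 0.0068.

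The textbook targets of CLF ask whether genes known to carry Polycomb marks were higher without it. AG, the floral organ identity gene that is ectopically active in clf leaves, was at 0.08 FPKM in wt leaves and 21.0 in clf-28 leaves, a log2 ratio of 4.35. SEP3, a partner of AG in floral organ identity, was at 4.91 FPKM in wt leaves and 49.5 in clf-28 leaves. FT, the mobile flowering signal, was at 1.0 and 18.1 FPKM in leaves, and at 6.76 and 23.1 FPKM in flowers. FLC, a repressor of flowering, was higher in clf-28 in all 4 organs: from 2.56 to 13.4 FPKM in roots, from 2.61 to 16.8 in leaves, from 3.73 to 6.36 in flowers and from 0.64 to 31.7 in siliques. MAF5, a relative of FLC, was higher in the 4 organs as well, with log2 ratios of 0.71 in roots, 2.2 in leaves, 1.65 in flowers and 0.81 in siliques. AGL19, which promotes flowering, went from 2.28 to 4.91 FPKM in roots and from 0.78 to 4.07 in leaves, and was under 1 FPKM in flowers and siliques.

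Some of these genes stood at similar or lower values in the reproductive organs, where wt expresses them. AG was at 43.2 FPKM in wt flowers and 48.8 in clf-28 flowers, and at 31.1 and 12.4 in siliques, a log2 ratio of -1.27. SEP3 was at 178 and 148 FPKM in flowers and at 186 and 75.3 in siliques, a log2 ratio of -1.29. STM, which maintains the shoot meristem, was at 2.31 and 3.21 FPKM in leaves, 41.2 and 42.0 in flowers, and 10.7 and 5.10 in siliques. FT was at 154 and 133 FPKM in siliques. In roots, AG was listed at 0 in wt and at 1.15 FPKM in clf-28, and FT and STM were near 0 in both. MAF4 was under 1 FPKM in each library. The authors' intervals overlapped for the textbook targets in each organ. AG lies on chromosome 4 (10382856 to 10388539), FLC on chromosome 5 (3173497 to 3179529), FT on chromosome 1 (24331428 to 24333934) and SEP3 on chromosome 1 (8593637 to 8596105).

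**Figure D1:**
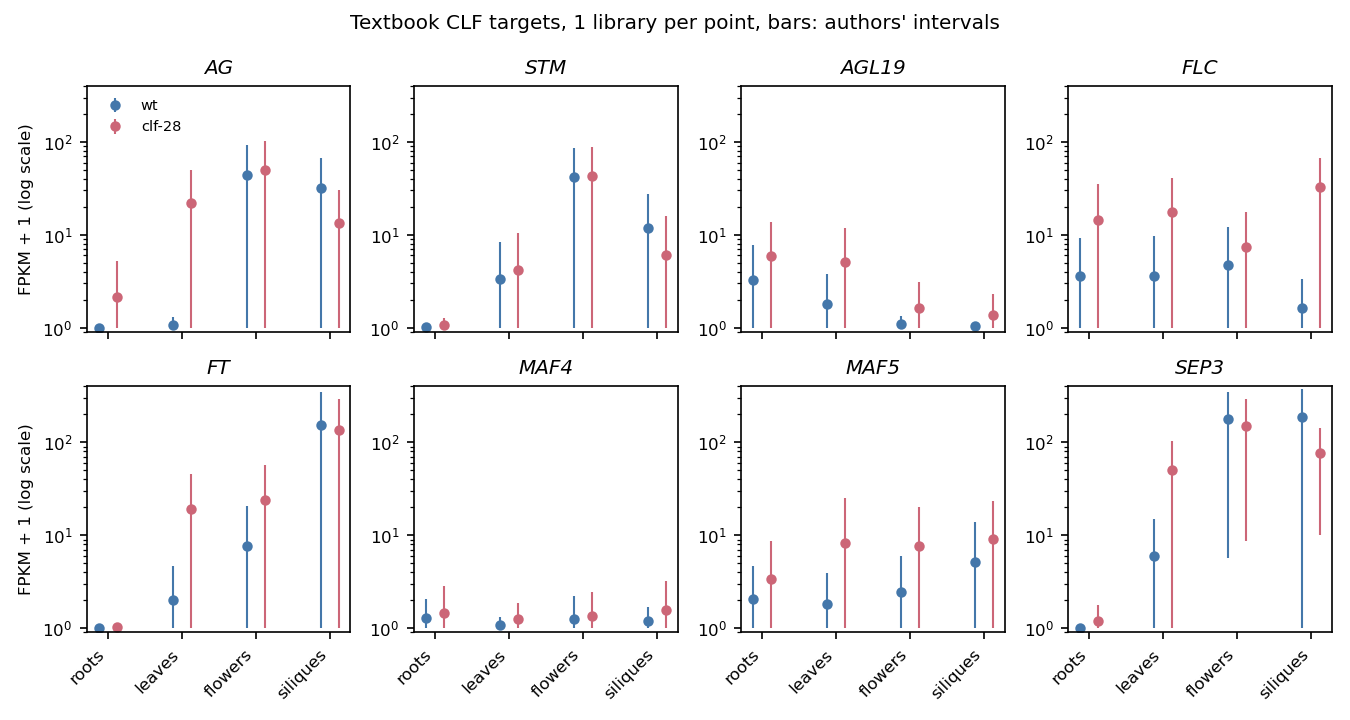
FPKM + 1 on a log scale for the 8 textbook targets in 4 organs, with 1 point per library (wt blue, clf-28 red) and the authors' interval as a bar. AG in leaves goes from 0.08 FPKM in wt to 21.0 in clf-28, while in flowers it is at 43.2 and 48.8.

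Which genes change the same way in the 4 organs was asked with limma. AT3G01345 (chromosome 3, 129138 to 130749) and MRD1 (AT1G53480, chromosome 1, 19963047 to 19974506) were almost absent from clf-28 in every organ: AT3G01345 went from 57.1 to 0.09 FPKM in leaves and from 81.2 to 0.33 in flowers, and MRD1 from 19.5 to 0.34 FPKM in flowers. Their mean log2 differences over 4 organs were -5.01 ± 1.32 (SD over organs) and -2.99 ± 0.72. On the other side, SADHU5-1 (AT4G01525, chromosome 4, 660810 to 661698), a copy of a Sadhu retroelement, had a mean log2 difference of 1.97 ± 0.31, and AT4G13575 (chromosome 4, 7886827 to 7898525) one of 3.59 ± 0.81. RAP2.6, an ERF transcription factor of stress responses, stood at 2.2 ± 0.43, AT5G56370 at 1.87 ± 0.35 and ZW9 at 1.42 ± 0.23. DEG14, AT2G40205 and XTH16, which remodels cell wall xyloglucan, had mean log2 differences of -0.80 ± 0.10, -0.84 ± 0.16 and -0.97 ± 0.22. These 10 genes had the smallest p in limma in their direction among genes with the same sign in 4 of 4 organs, and none passed: the adjusted p was 0.414 for each.

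By limma, 0 of 24078 genes passed an adjusted p of 0.05 over the 4 organs. At an unadjusted p under 0.05 there were 1323 genes higher and 1516 lower in clf-28, against 1204 expected by chance over both directions. That count rested on leaves, without which it was 602 higher and 631 lower, and the balance turned without roots, with 1055 higher and 764 lower. With quantile scaling it was 1068 higher and 1936 lower. The sign was the same in the 4 organs for 5887 genes (24.4%), where independent signs would give 12.5%. The call of single genes rested on settings: AT4G13575 passed with a pseudocount of 5 (adjusted p = 0.0104 in limma), and AT3G01345 passed without siliques (adjusted p = 0.0404 in limma).

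Gene lists were compared over the 4 organs with camera. The textbook targets rose, with a median log2 difference of 1.09 over 7 genes (adjusted p = 0.0107), led by FLC at 2.32 (SE 0.60), MAF5 at 1.34 (SE 0.29) and FT at 1.17 (SE 0.63). The call was lost with an estimated correlation (adjusted p = 0.679 with an estimated correlation) and without leaves (median 0.48, adjusted p = 0.0723 in camera). Adjusted over the list alone, 3 of these genes were higher (FLC, MAF5 and AGL19) and 0 lower. The flowering time list rose with a median of 0.24 over 21 genes (adjusted p = 0.0134), which was lost as well (adjusted p = 0.679 with an estimated correlation). Adjusted over the list alone, 5 genes were higher (FLC, MAF5, AGL19, AGL17 and AGL42) and 1 lower. The lower gene was SVP, a repressor of flowering, with a log2 difference of -0.81 (SE 0.10). FLC represses flowering, and AGL17, AGL19 and AGL42 promote it, so the members that were higher do not act in 1 direction. FLC, MAF5, FT and AGL19 stand in both lists.

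The list of cold, drought and ABA response rose with a median of 1.1 over 14 genes (adjusted p = 8.68e-04 in camera), led by the dehydration genes KIN1 at 2.63 (SE 0.79) and RD29B at 2.09 (SE 0.81). Its median was 0.63 without leaves, and the call was lost with an estimated correlation (adjusted p = 0.679 with an estimated correlation). Embryo and seed maturation regulators rose with a median of 0.42 over 15 genes (adjusted p = 0.0121), with bZIP67 at 1.31 (SE 1.01) and ABI3 at 1.06 (SE 0.86). That call was lost with an estimated correlation (adjusted p = 0.816 with an estimated correlation), and the direction rested on siliques, without which the median was -0.089. Photosynthesis genes fell: the median of 15 genes was -0.80 (adjusted p = 1.86e-07), 12 of them were lower in all 4 organs, and the Rubisco small subunit genes RBCS2B and RBCS1B stood at -1.23 (SE 0.28) and -1.12 (SE 0.29). This call too was lost (adjusted p = 0.679 with an estimated correlation). Adjusted over the list alone, 0 genes of the cold, embryo and photosynthesis lists passed in limma, where 4 cold response genes were higher and 10 photosynthesis genes lower at an unadjusted p under 0.05, and 0 embryo regulators.

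The other 12 lists did not pass in camera over the 4 organs. Seed storage, oleosin and LEA had a median of 1.67 (adjusted p = 0.0516), heat shock 0.46 (adjusted p = 0.0642), Polycomb and related factors 0.10 (adjusted p = 0.0873), floral organ identity 0.18 and anther and pollen -0.16 and auxin -0.11 (adjusted p = 0.106 each), and defence and jasmonate 0.29 (adjusted p = 0.239). Fatty acid and oil synthesis had a median of 0.08 (adjusted p = 0.535), reference genes -0.03 (adjusted p = 0.704), KNOX and meristem -0.05 (adjusted p = 0.705), endosperm and seed coat -0.12 (adjusted p = 0.859) and root and root hair 0.02 (adjusted p = 0.977). For 8 of these lists the side of the threshold turned on single organs. Seed storage passed as higher without roots, leaves or flowers (adjusted p = 0.00258, 0.0194 and 0.0390 in camera). It passed as lower without siliques (median -0.68, adjusted p = 0.00544 in camera). That fall lay in roots, where the median over 14 genes was -1.64, against 0.070 in leaves and 0.029 in flowers. Without siliques, oil synthesis (-0.16, adjusted p = 8.37e-04) and auxin (-0.23, adjusted p = 0.0107) passed as lower, and floral organ identity (0.31, adjusted p = 2.59e-04) and endosperm and seed coat (0.18, adjusted p = 0.0388) as higher, while heat shock stood at 0.065. Floral organ identity stood at -0.038 without leaves. Heat shock passed as higher without flowers or leaves (adjusted p = 0.0174 and 0.0194), and without roots Polycomb factors passed as higher (adjusted p = 0.0417) and auxin and anther and pollen as lower (adjusted p = 0.0234 and 0.0496). Median and mean differed in sign for KNOX and meristem (mean 0.08), endosperm and seed coat (mean 0.02) and root and root hair (mean -0.01), and camera gave each of these 3 the direction up. Adjusted over the list alone, 0 genes passed in these 12 lists in limma, and at an unadjusted p under 0.05 their 214 entries held 3 higher and 9 lower. In fry, which asks whether the genes of a list move at all, 0 lists passed for a change in 1 direction, and flowering time and reference genes passed for change in either direction (adjusted p = 0.0286 each). The reference genes with the largest differences were GAPC1 at -0.43 (SE 0.15) and UBQ10 at 0.26 (SE 0.20).

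Whether the clf-28 effect differed between stages was tested with the nested fit. In the seedling organs, cold response genes rose with a median log2 difference of 2.0 (camera adjusted p = 1.5e-11), with RD29A at 4.01 and KIN1 at 3.71. That call was lost with an estimated correlation (adjusted p = 0.684 with an estimated correlation). Textbook targets rose by 1.63 (adjusted p = 1.73e-04), floral organ identity by 0.29 (adjusted p = 5.71e-05) and flowering time by 0.35 (adjusted p = 6.68e-04), and these 3 were lost as well (adjusted p = 0.684 with an estimated correlation for each). Over the same genes, the medians in roots and in leaves were 1.06 and 3.14 for cold response, 0.71 and 2.30 for textbook targets, 0.13 and 0.49 for floral organ identity, and 0.13 and 0.70 for flowering time. Photosynthesis had a median of -0.89 in seedling organs (adjusted p = 4.44e-05) and of -0.83 in reproductive organs (adjusted p = 8.26e-05), and neither call held (adjusted p = 0.798 and 0.906 with an estimated correlation). Within each stage the organs differed, with medians of -1.39 in roots and -0.29 in leaves, and of -0.14 in flowers and -1.33 in siliques. In the reproductive organs, seed storage genes rose with a median of 4.16 (adjusted p = 8.26e-05), embryo regulators with 0.90 (adjusted p = 1.10e-04), oil synthesis with 0.47 (adjusted p = 0.00351) and Polycomb factors with 0.17 (adjusted p = 0.00748), and anther and pollen genes had a median of -0.33 (adjusted p = 0.00598). None of these 5 calls held (adjusted p = 0.906 with an estimated correlation for each). Each stage value averages the organs: in flowers the medians were 0.029 for seed storage, -1.06e-04 for embryo regulators and -0.028 for oil synthesis, against 8.39, 1.76 and 0.99 in siliques. Polycomb factors stood at 0.055 in flowers and 0.29 in siliques, and anther and pollen genes at -0.68 in flowers and 1.66e-04 in siliques. Of 21 anther and pollen genes, 0 were measured in roots, 0 in leaves and 3 in siliques. Their medians near 0 in those organs come mostly from genes hardly expressed there. Of 17 embryo regulators, 5 were measured in roots, 4 in leaves and 6 in flowers. By limma, 0 genes passed in either stage. The unadjusted count was 1164 higher and 1038 lower genes in seedling organs and 754 higher and 827 lower in reproductive organs, against 1204 expected by chance in each stage over both directions.

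The difference between stages, reproductive minus seedling, passed in camera for 9 lists, and for none of them with an estimated correlation (adjusted p = 0.576 with an estimated correlation for each). The estimated form rested on 2 residual degrees of freedom, so the loss is not due to correlation alone. Cold response stood at -2.16 (adjusted p = 8.8e-09), floral organ identity at -0.72 (adjusted p = 6.07e-05), textbook targets at -0.70 (adjusted p = 0.0141), flowering time at -0.57 (adjusted p = 0.0128) and anther and pollen at -0.35 (adjusted p = 0.00785). Seed storage stood at 4.72 and oil synthesis at 0.74 (adjusted p = 9.17e-05 each), embryo regulators at 0.98 (adjusted p = 0.00186) and Polycomb factors at 0.14 (adjusted p = 0.0424). By limma, 0 of 24078 genes passed for the difference, with 394 higher and 652 lower at an unadjusted p under 0.05, against 1204 expected by chance over both directions. No difference between stages was called for photosynthesis (median 0.08, camera adjusted p = 0.957).

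In roots, 6 rises and 1 fall had authors' intervals that did not overlap. JAZ10, a repressor of jasmonate signalling (AT5G13220, chromosome 5, 4218888 to 4220883), was at 2.69 FPKM in wt roots and 68.6 in clf-28 roots, and OPR3, an enzyme of jasmonate synthesis (AT2G06050, chromosome 2, 2359114 to 2362302), at 24.0 and 117. The bHLH gene AT1G62975 was at 14.9 and 276 FPKM, and CYP708A2, which modifies the root triterpene thalianol (AT5G48000, chromosome 5, 19444138 to 19447850), at 14.2 and 149. AT5G05060 was at 12.7 and 120 FPKM and AT1G78070 at 20.5 and 138. The single fall with separate intervals was FRO2, the root ferric reductase (AT1G01580, chromosome 1, 209289 to 213086), at 149 FPKM in wt and 35.3 in clf-28.

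Among the lists in roots, cold response had a median log2 ratio of 1.52 (percentile 100), with 7 of 11 measured genes at least 2-fold higher, among them HVA22D at 3.71 and RD29A at 3.32. Flowering time had a median of 0.56 (percentile 100) with 3 of 14 higher: FLC at 2.01, SOC1 at 1.87 and AGL17 at 1.16. Floral organ identity had a median of 1.1 over 5 genes (percentile 99.9), with SEP4 at 1.24 and PI at 1.18. Heat shock stood at 0.72 (percentile 99.6), led by HSP70 at 2.35 with 1 of 6 genes past the rule of size, and defence and jasmonate at 0.49 (percentile 99.8), with the immunity genes EDS5 (7.57 to 28.9 FPKM) and FMO1 (1.75 to 6.64 FPKM) among 3 of 8 higher. In the same libraries, 13 genes of fast response to touch or wounding, listed after the first results, had a median of 1.27 (percentile 100). On the lower side, 14 of 15 seed storage genes (median -2.18, percentile 0, SESA5 at -3.55, SESA3 at -3.35) and 23 of 26 photosynthesis genes (median -1.41, percentile 0, LHCB3 at -2.20, LHCB1.2 at -2.15) were at least 2-fold lower in clf-28 roots. Oil synthesis (median -0.28, percentile 0.02, MOD1 at -0.66, BCCP2 at -0.57) and root and root hair genes (median -0.27, percentile 1.06, IRT1 at -1.23, NIP2.1 at 0.71) lay below most random lists with 0 and 1 genes past the rule. Polycomb factors, KNOX and meristem, embryo regulators, auxin and reference genes lay inside the central 95% in roots. In total 1096 genes were at least 2-fold higher and 240 lower among 19742 measured in roots, and the authors' intervals were apart for 6 and 1 of them.

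In leaves, 10 rises had authors' intervals that did not overlap, of which the 6 largest are named. LEA7, a late embryogenesis abundant protein (AT1G52690, chromosome 1, 19619745 to 19623461), was at 0.43 FPKM in wt leaves and 182 in clf-28 leaves, a log2 ratio of 7.0. AFP3, a partner of the ABA regulator ABI5 (AT3G29575, chromosome 3, 11382214 to 11384004), was at 5.68 and 69.6 FPKM. AT1G78070 was at 20.5 and 220 FPKM, OPR3 at 11.8 and 126, the protein phosphatase 2C gene AT3G05640 at 7.81 and 83.2, and AT1G69480 at 0.65 and 13.6. In 0 genes was the fall large enough for the authors' intervals to be apart.

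The lists in leaves were led by cold response (median 3.14, percentile 100, 10 of 14 higher), with RD29B at 4.95, RD29A at 4.70 and KIN1 at 4.68. Textbook targets had a median of 2.30 (percentile 100), with 6 of 7 at least 2-fold higher, and floral organ identity one of 1.88 (percentile 100), with 6 of 8 higher, among them AG at 4.35, SEP3 at 3.09 and the carpel gene SHP2 at 2.34. Flowering time stood at 0.74 (percentile 100) with 9 of 19 higher: FT at 3.25, AGL17 at 3.23 and FLC at 2.30 were the largest. Defence and jasmonate had a median of 0.41 (percentile 99.4), with LOX2 at 1.87 and PR1 at 1.41. The 13 genes of fast response to touch or wounding had a median of 0.63 in leaves (percentile 100). Auxin genes had a median of -0.46 (percentile 0.01), with IAA1 at -1.20 and GH3.5 at 1.18, and oil synthesis one of -0.21 (percentile 1.0), with DGAT1 at 1.1 and BCCP2 at -0.86. Photosynthesis lay inside the central 95% in leaves (median -0.29, percentile 10.4), with 15 of its 26 genes measured. LHCA1, LHCA3 and PSBO1 of that list had too many reads in wt leaves alone, so the median leaves out some abundant members. Polycomb factors, KNOX and meristem, root and root hair and reference genes lay inside the central 95% as well. In total 1009 genes were higher and 264 lower among 18509 measured in leaves, with intervals apart for 10 and 0.

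In flowers the differences were fewer. BT2, a scaffold protein of nutrient and light responses (AT3G48360, chromosome 3, 17905528 to 17910662), was at 0.74 FPKM in wt flowers and 20.8 in clf-28 flowers, and DYL1, a dormancy-associated gene (AT1G28330, chromosome 1, 9933688 to 9935271), at 63.5 and 337. A merged locus of AT4G13493, AT4G13494 and AT4G13495 on chromosome 4 (7842882 to 7848106) was at 35.2 and 303 FPKM. LHY, a morning gene of the circadian clock (AT1G01060, chromosome 1, 33379 to 37871), was the single fall with separate intervals, at 61.2 FPKM in wt and 13 in clf-28.

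Among the lists in flowers, anther and pollen genes had a median log2 ratio of -0.68 (percentile 0). At least 2-fold lower were 2 of 18, ATA7, expressed in the tapetum, at -1.09 and the tapetum regulator AMS at -1.02. Not all members fell, as VGDH1 stood at 0.33 and VGD1 at 0.11, and AGL66 at -0.14 and HTR10 at -0.16 fell only slightly. These 4 were chosen after their values were seen. Textbook targets (median 0.40, percentile 99.6) had 2 of 6 higher, and flowering time (median 0.23, percentile 99.9) had 3 of 18 higher, MAF5 at 1.65, FT at 1.64 and AGL17 at 1.11. Floral organ identity stood at 0.14 (percentile 97.7) with 0 of 19 genes past the rule, and AP1 at -0.81 and SUP at 0.73 were its largest values. Cold response stood at 0.23 (percentile 99.2), with COR15B at 25.8 and 60.7 FPKM and HVA22D at -0.71. KNOX and meristem had a median of -0.19 (percentile 1.11), with WOX1 at -0.63 and PRS at -0.57, and auxin also -0.19 (percentile 0.53), with IAA19 at -0.90. The other lists with a median in flowers lay inside the central 95%, among them photosynthesis at -0.06 and endosperm and seed coat at 0.24. In total 315 genes were higher and 217 lower among 20926 measured in flowers, with intervals apart for 3 and 1.

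In siliques, 41 rises had authors' intervals that did not overlap, of which the 6 largest are named. AT1G04560, of the AWPM-19 membrane protein family (chromosome 1, 1244799 to 1246059), was at 0.48 FPKM in wt siliques and 985 in clf-28 siliques. AT2G15010 was at 0.74 and 259 FPKM, the sucrose synthase SUS2 of developing seeds (AT5G49190, chromosome 5, 19943216 to 19947655) at 1.27 and 312, and AT3G56350, a manganese superoxide dismutase gene, at 0.05 and 137. AT5G44310, of the LEA family, was at 0.04 and 68.5 FPKM and AT2G18540 at 0.02 and 63.2. The single fall with separate intervals was BAS, the beta-amyrin synthase (AT1G78950, chromosome 1, 29684289 to 29688851), at 60.8 FPKM in wt and 6.89 in clf-28.

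The seed storage list had a median log2 ratio of 8.39 in siliques (percentile 100) and 14 of 14 measured genes were higher. The 2S albumin SESA5 was listed at 0 in wt and at 4028 FPKM in clf-28, SESA1 stood at a log2 ratio of 11.74 and the oil body protein OLEO1 at 10.75. Embryo and seed maturation regulators had a median of 1.76 (percentile 100) with 12 of 15 higher, led by bZIP67 at 5.17, the dormancy gene DOG1 at 4.91 and ABI3 at 4.36. Oil synthesis had a median of 0.99 (percentile 100) with 14 of 29 higher, among them SUS2 at 7.11 and FAE1, which elongates seed fatty acids, at 6.53. KNOX and meristem stood at 0.54 (percentile 99.4), with PLT5 at 3.89 and PLT3 at 2.08, and heat shock at 1.85 (percentile 99.97) with 6 of 6 higher, HSP17.4 at 2.62 and HSP70 at 2.58. Polycomb factors stood at 0.29 (percentile 98.3), with ULT1 at 14.1 and 36.1 FPKM, BMI1A at a log2 ratio of 1.26 and VAL1 at 1.25 among 5 of 23 higher. CLF itself is a member of that list and 1 of the 5.

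Markers of the seed coat, endosperm and green tissue moved with these genes in siliques. Endosperm and seed coat genes had a median of -1.05 (percentile 0), with 9 of 17 lower and 4 higher: TT10, the laccase of late seed coat browning, stood at a log2 ratio of 3.53, and the transporter TT12 of the young seed coat went from 50.1 to 11.8 FPKM. The auxin synthesis gene YUC10 stood at 1.94. Photosynthesis genes had a median of -1.37 (percentile 0) with 22 of 24 lower, RBCS2B at -2.10 and RBCS1B at -1.96. Floral organ identity stood at -0.56 (percentile 0.69) with 4 of 15 lower, SEP3 at -1.29 and AG at -1.27, and SPT at 1.76 the single gene past the rule on the higher side. Auxin stood at -0.51 (percentile 0.27), with YUC4 at 1.93 and TAA1 at 1.74 among 3 higher and 2 lower genes of 15. Textbook targets (median -0.58, percentile 4.78), flowering time (0.03, percentile 58.2), defence and jasmonate (-0.28, percentile 11), cold response (-0.38, percentile 8.15), root and root hair (-0.03, percentile 42.4) and reference genes (-0.06, percentile 67.8) lay inside the central 95%. In total 2382 genes were higher and 1671 lower among 20892 measured in siliques, with intervals apart for 41 and 1. Over the 4 organs, 33 of 57 list medians lay outside the central 95%, 20 higher and 13 lower. The random lists hold independently drawn genes, while genes of a list can move together. Residual correlations were estimated at 0.92 for photosynthesis and 0.93 for seed storage. With 1 library per group, a percentile cannot tell genotype from any other difference between the libraries.

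**Figure D2:**
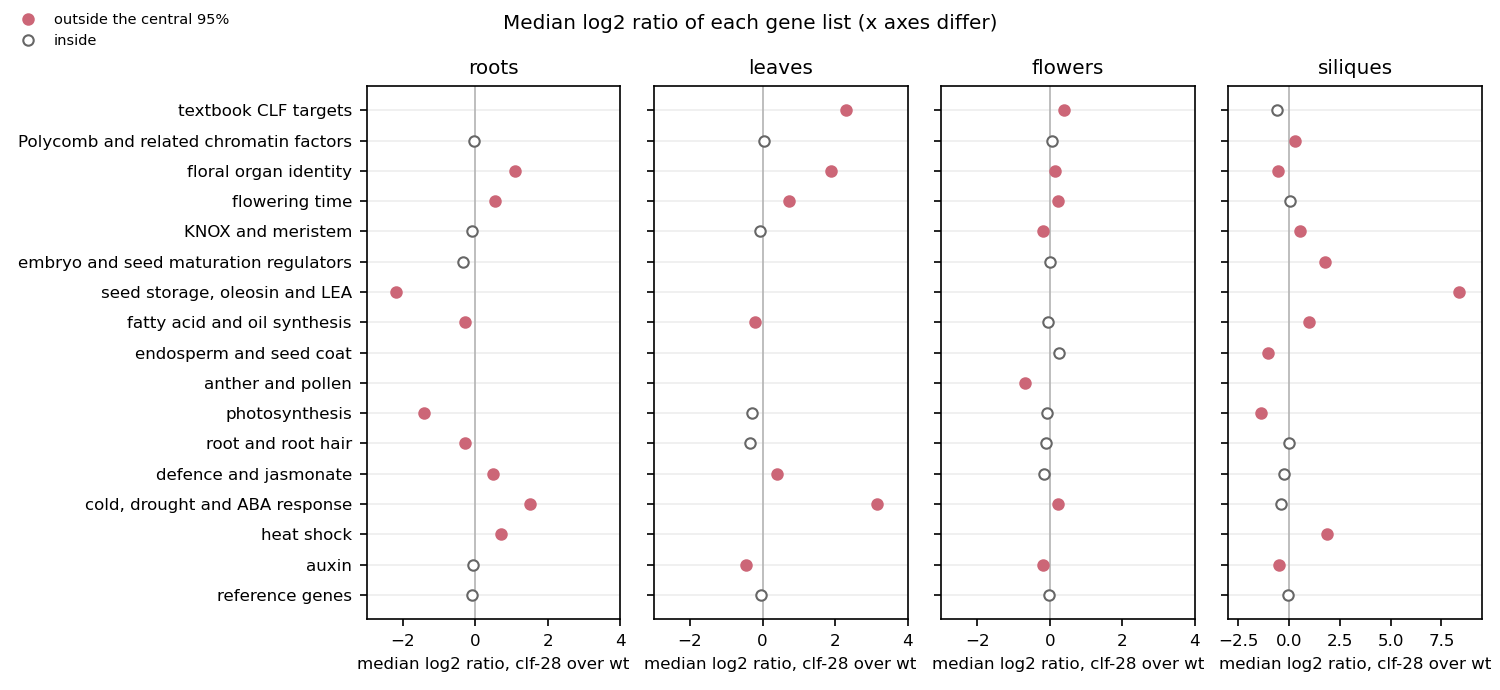
Median log2 ratio, clf-28 over wt, of each gene list with at least 5 measured genes in each organ. Filled points lie outside the central 95% of 10000 random lists and open points inside; seed storage is at 8.39 in siliques and -2.18 in roots, and cold response at 3.14 in leaves.

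**Figure D3:**
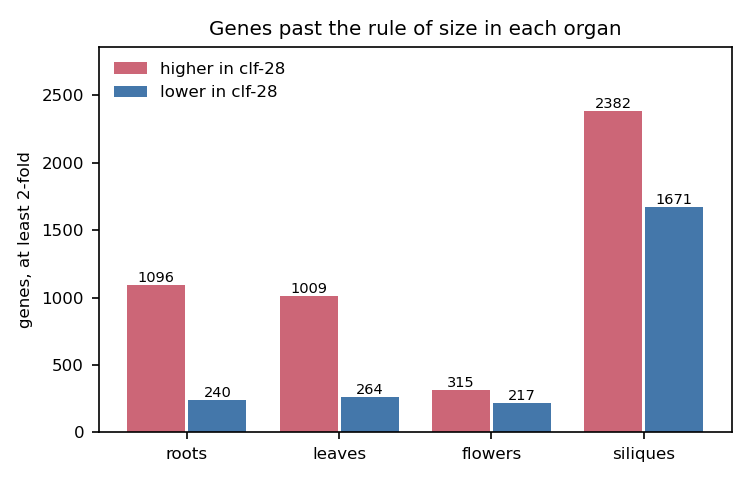
Number of genes at least 2-fold higher (red) or lower (blue) in clf-28 in each organ, from 2 libraries per organ. Roots and leaves have 1096 and 1009 higher against 240 and 264 lower genes, and siliques 2382 and 1671.

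The split of the genes past the rule of size leaned to the higher side in each organ, with 82.0% of them higher in roots, 79.3% in leaves, 59.2% in flowers and 58.8% in siliques. Between organs, roots and leaves shared 345 higher genes where independent sets would share 40.1, and 22 lower genes where 2.02 would be shared. Leaves and siliques shared 323 higher genes (80.0 if independent), roots and siliques 299 (80.4), flowers and siliques 119 (25.1), leaves and flowers 80 (13.9), and roots and flowers 49 (10.8). Genes higher in one organ and lower in the other were also more than independent sets would give: 36 for roots and flowers (7.27 if independent), 126 for roots and siliques (62.7), 57 for flowers and siliques (34.9), 28 for leaves and flowers (10.7), 91 for leaves and siliques (75.9) and 22 for roots and leaves (18.0). In 2 or more organs 819 genes were higher and 195 lower. Across the 17278 genes measured in both, log2 ratios of roots and leaves had a Pearson r of 0.55 and a Spearman rho of 0.52, and the r of the other pairs of organs ran from 0.09 to 0.27. These correlations are across genes, and genes are not independent replicates.

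At least 2-fold higher in all 4 organs were 14 genes (0.0327 expected from independent sets), and 2 were lower (0.00049 expected). The lower genes were AT3G01345 and MRD1. The higher genes beyond those already named over organs, chosen after their values were seen, were AT2G15960, SIP2, AT1G06620, IGMT5, DREB2A, AGL17, COR27, AT4G28140 and LEA7. DREB2A, a transcription factor of drought and heat response, was at 4.70 FPKM in wt leaves and 40.9 in clf-28 leaves, and AGL17, a MADS box gene of roots, at 0.03 and 8.64 FPKM in leaves. AGL17 lies on chromosome 2 (9618210 to 9621957), as do CLF and SVP (9579630 to 9583893). Without siliques, 428 genes were higher and 39 lower in 2 or more organs.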

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

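In this part, the tests on early seed coat genes, on embryo genes in siliques and on seed storage genes in the other organs were chosen only after the result was seen.

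For 9 gene lists the clf-28 effect in flowers and siliques differed from that in roots and leaves by the test of the difference itself in camera, and for none of them with an estimated correlation (adjusted p = 0.576 with an estimated correlation). The adjusted p was 9.17e-05 for seed storage, oleosin and LEA, 9.17e-05 for fatty acid and oil synthesis, 0.00186 for embryo and seed maturation regulators and 0.0424 for Polycomb factors, all 4 with the higher effect in the reproductive organs. For the first 3 of these lists that effect lay in siliques, as the medians in flowers were 0.029, -0.028 and -1.06e-04. Only 4 of 20 seed storage genes and 6 of 17 embryo regulators were measured in flowers. The adjusted p was 8.8e-09 for cold, drought and ABA response, 6.07e-05 for floral organ identity, 0.0128 for flowering time, 0.0141 for textbook CLF targets and 0.00785 for anther and pollen, with the lower effect in the reproductive organs. For anther and pollen, 0 of 21 genes were measured in roots or in leaves. That difference therefore only restates the lower values in flowers (median -0.68). Stage, growth on plates or in soil and organ changed together, so no difference can be credited to stage or growth alone. Where it lay in 1 organ of a stage, as for seed storage in siliques, it rested on 1 library per genotype.

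The status column, which the comparisons used only as a filter, held 1 more signal. In siliques, 7 genes were listed at 0 for too many reads in clf-28 alone, with usable wt values between 0.02 and 8.37 FPKM. They were the seed storage genes CRA1, CRU2, CRU3, SESA2, SESA3 and SESA4, and AT2G27380. They had dropped out of the counts and medians as not measured, although their reads in clf-28 exceeded what Cufflinks would process. In wt siliques alone 17 loci had that status, among them LHCB1.3, RBCS1A and a stretch of neighbours of AT4G12870 and AT4G12960.

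For the seed storage genes in siliques, a release in every organ is argued against. The highest median log2 ratio of the storage list among roots, leaves and flowers was 0.070. Of the 20 genes only 3 in leaves and 4 in flowers were measured, and these medians were known beforehand. A release limited to seeds was not tested. Older seeds in the clf-28 pool may account for the rise in siliques. The early seed coat genes BAN, TT2, TT12 and TT16 had a median of -1.42, while TT10, of late seed coats, stood at 3.53. Mitosis genes, set to lie at or below -1 with older seeds and above -0.5 otherwise, had a median of 0.46 and met the condition against older seeds. That condition assumed an equal share of embryo in both pools, which is not shown: BBM, PLT3, PLT5, WOX8 and WOX9, active in embryos, had a median of 1.89 in clf-28 siliques, though WOX8 stood at 0.60, LEC1 at 0.29 and LEC2 at 0.50, so the seed coat and mitosis genes together leave the age of the seeds open. Seeds of several ages in 1 pool, and an effect of clf-28 on seed development or on the time of flowering, were not tested and stay open.

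Cold, drought and ABA genes in roots and leaves were weighed next. Handling at harvest could account for it: 13 genes that respond fast to touch or wounding had a median log2 ratio of 1.12 over their 26 values in roots and leaves. That median was 1.27 in roots, 0.63 in leaves and 2.28 in siliques, and the cold response list stood highest in leaves (3.14) and at -0.38 in siliques. For another time of day at harvest, 5 of 22 values of 11 clock genes were at or beyond 1 on the log2 scale, between the bounds set for and against it, and cannot be told apart from a clf-28 effect with 1 library per group. A clf-28 effect on stress genes was not tested apart from these and stays open.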

How the results depend on the processing

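The overlap and the lists within organs without siliques, and the settings for CLF, were chosen only after the result was seen. The libraries were paired by organ, since the labels give no replicate numbers, and without that block limma gave 0 genes as well (147 higher and 13 lower at an unadjusted p under 0.05). Without depth, the authors' intervals limit every call within an organ, and the added demand that they be apart left 7 genes in roots, 10 in leaves, 4 in flowers, 42 in siliques and 3 shared by 2 or more organs, since few lower bounds exceed 0. A pseudocount of 5, which shrinks genes of low FPKM by construction, gave 719 genes in roots, 624 in leaves, 220 in flowers, 2173 in siliques and 448 shared, and 1 gene over organs in limma. A pseudocount of 0.1 gave 913 genes in flowers. The overlap without siliques was 467 genes, where fewer organs were compared. Leaving out each organ gave 0 to 1 genes over organs, with 1 without siliques, and 6 to 9 gene lists, with 9 without roots or without siliques; 0 lists passed with an estimated correlation. Without siliques the medians of embryo regulators (range -0.089 to 0.62), seed storage (-0.68 to 2.83) and oil synthesis (-0.16 to 0.17) turned negative. Seed storage and oil synthesis then passed as lower (adjusted p = 0.00544 and 8.37e-04 in camera), and the cause was not tested. For seed storage that fall lay in roots, with a median of -1.64 there against 0.070 in leaves and 0.029 in flowers. For oil synthesis the medians were -0.28 in roots, -0.20 in leaves and -0.028 in flowers. Of the 73 alternative counts 56 stayed within 1.5 times the reported one. Genes named per organ kept their direction in 72 of 72 alternatives. They had been picked for large ratios with separate intervals, so a turn was unlikely by construction. Genes named over organs kept direction and side of the threshold in 231 of 233, and none of them had passed in the main fit. Lists over organs were counted as unchanged in 81 of 101, and 6 lost and 11 gained a call in the same direction. In the other 3, all without siliques, direction turned in lists that passed in the main fit or in the alternative. Turns of the camera direction in lists that passed in neither were counted as unchanged. They were KNOX and meristem without siliques, root and root hair without roots or siliques, and endosperm and seed coat without leaves or flowers. List medians within organs moved in 3 of 114, all with a pseudocount of 0.1. Dropping the filter left the counts within organs as they were by construction.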

Other observations

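In this part, the gene lists, the test of a deletion and the splits of the libraries were chosen only after the result was seen.

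Genes of jasmonate synthesis and signalling were higher together in clf-28 roots and leaves. Of 14 such genes, 14 were at least 2-fold higher in roots (median log2 ratio 2.74, percentile 100) and 14 in leaves (2.96, percentile 100), with 0 of 14 in flowers (0.28, percentile 99.96) and 6 of 13 in siliques (0.82, percentile 99.93). The repressor gene JAZ8 was at 1.34 FPKM in wt roots and 30.3 in clf-28 roots. The lipoxygenase LOX3, which starts jasmonate synthesis, was at 2.04 FPKM in wt leaves and 48.1 in clf-28 leaves, and the allene oxide cyclase AOC3 at 0.52 and 31.3. In the same libraries 13 genes of fast response to touch or wounding, which also induces jasmonate synthesis, had medians of 1.27 in roots and 0.63 in leaves (percentile 100 in both), with -0.36 in flowers and 2.28 in siliques. Mitosis genes had medians of -0.59 in roots and -0.73 in leaves (percentile 0 in both), -0.19 in flowers (percentile 0.33) and 0.46 in siliques (percentile 98.97) over 14 genes, and 0 of them were past the rule of size.

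Genes of iron deficiency went in opposite directions in different organs. In flowers 10 of 12 were at least 2-fold higher in clf-28 (median 3.18, percentile 100): the peptide genes IMA2 and IMA3 were at 3.02 and 1.07 FPKM in wt and at 289.8 and 107 in clf-28, and bHLH38, a regulator of iron uptake, at 0.02 and 26.2. In siliques 7 of 9 were higher (1.94), and in roots 4 of 11 were lower (-0.78, percentile 0), among them FRO2 and bHLH100 (15.2 to 2.85 FPKM). In leaves 0 of 12 were past the rule of size, with a median of 0.30 (percentile 98.6). The ferritin genes FER1, FER3 and FER4, which store iron, had medians of -1.0 in flowers, -1.01 in siliques, -0.20 in roots and 0.46 in leaves. Of 11 clock genes in flowers, 5 were higher and 3 lower, with the evening gene PRR5 at 2.06 and 21.8 FPKM and LHY at 61.2 and 13 FPKM. The higher genes were PRR5, TOC1, ELF4, FKF1 and ELF3, and the lower ones CCA1, LHY and RVE8. In siliques 2 of the 11 were higher, TOC1 and ELF4, and 3 lower, CCA1, LHY and CDF1. Another time of day at harvest was not tested for flowers and siliques and stays open. SVP was lower in clf-28 in each organ, from 27.7 to 18.5 FPKM in roots, from 69.3 to 37.7 in leaves, from 8.39 to 3.89 in flowers and from 2.09 to 0.69 in siliques. Photosynthesis genes were lower in clf-28 roots, as LHCB3 at 50.8 and 10.3 FPKM.

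For the 16 genes at least 2-fold higher or lower in all 4 organs, a chromosome segment of other origin linked to CLF is argued against as the source of the set, since 1 of the 16 (AGL17) lay within 2 Mb of CLF and 0.58 would by chance. For AGL17 alone, such a segment was not tested and stays open. It was not tested and stays open as well for SVP, which lies near AGL17 and CLF on chromosome 2 (9579630 to 9583893). SVP was lower in each organ without passing the rule of size, which is set on FPKM + 1. Its log2 ratio was -0.94 in flowers and -0.87 in siliques, where the FPKM itself fell more than 2-fold. A deletion of AT3G01345 and MRD1 in the clf-28 line might account for their near absence. Their highest value in a clf-28 library was 0.82 FPKM, neither 0 in all 4 nor above the bound of 1 set against a deletion, and reads that also match other loci cannot be set aside without the alignments, so a deletion and silencing cannot be told apart here. An effect of clf-28 on these genes was not tested apart from this and stays open.

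The genotype labels were compared with the other splits of the 8 libraries that part the 4 organ pairs. There are 8 such splits, too few for a share under 0.05, as the smallest is 0.125. The other splits swap wt and clf-28 in 1 or 2 organs. They hold the same differences between the genotypes with other signs, so their counts are no measure of chance. The real split gave 2839 genes at an unadjusted p under 0.05 and the highest of the others 1430, so that 1 of the 8 gave as many. At an adjusted p under 0.05, 8 of the 8 gave as many, with 0 genes in the real split and 0 in the highest other. A count of 0 in the real split fixed that outcome in advance. For gene lists 7 of the 8 gave as many, with 5 in the real split and 10 in the highest other. Splits that part only 2 pairs gave up to 3033 genes and 12 lists. With organ as a block, only the 2 parted pairs enter their estimate. The split with 3033 genes parted leaves and siliques with wt on the same side in both. It is therefore the clf-28 contrast in those organs and not a grouping that goes against the labels.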
